A study of Mus musculus with 2 samples.

How the data were processed

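DNase-seq libraries from the right cerebral cortex of 2 female B6CASTF1/J mice aged 10 days were used, 1 library per animal, forming 1 group. The labels number the animals separately and call the libraries biological replicates, while both carry the same donor entry. The libraries were treated as coming from 2 animals on the basis of that numbering. Whether the animals share a litter is not known. With 1 group, no test between conditions was made, and every p-value compares genes or sites within a library, not animals. Values from both libraries are given as mean ± SD with n = 2.

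Per the file headers, the authors called peaks on each library separately on the mm10 assembly, from that library's alignments, and deposited 2 peak lists per library. The aligner, the peak and footprint callers and their versions are not given in the sources used here. The deposited signal of a peak is its height, and it is used only to describe, rank or compare peaks. The heights are whole multiples of a small step in each library (within 0.05 of a step for 100% of heights under 1), 2.08 times larger in replicate 2, from which heights were taken to be scaled by the authors to the depth of each library. The sources used here do not state this scaling. The deposited base-wise p-value column is a false discovery rate (FDR) of the cut rate and lists only bases at 0.05 or less. Every peak of the smaller list held a base at 0.001 or less, as tested on the files, so it is called the stricter list. The footprint files deposited by the authors carry a constant p-value of 0.01, a threshold rather than a value per footprint.

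The main list was to be the one with narrower elements. Median widths tied within each library (180 and 180 bp in replicate 1, 200 and 200 bp in replicate 2), so the rule did not decide, and the stricter list was used in both. The larger list (210497 and 119314 peaks) is an alternative. Depth in reads was not used here. A promoter without a peak means none at the authors' threshold, which a shallower library misses more often, and no limit from counts can be given.

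Annotation came from GENCODE vM21 and sequence from GRCm38.p6, the assembly of which mm10 is the browser name. Peaks were used on the 19 autosomes, X and Y. Overlap needed 1 bp and was compared with 20 random placements on the same chromosomes (bedtools 2.31.1). Peak centres were assigned to promoters (500 bp on either side of a protein-coding start site), exons, introns or intergenic sequence, in that order, all by protein-coding genes, so that intergenic sequence includes other annotated genes. The height at a promoter is that of the highest peak overlapping the window of 500 bp around any annotated start site of the gene. This peak can be a different site in each library. A gene without such a peak in a library was given a height of 0 there, which enters its mean and SD.

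Before the data were examined, 20 gene lists and 21 motif consensus sequences were fixed, with the tests and the rule for genes named in the text. Ahsp, of the erythroid list, was not in the annotation. Lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, Benjamini-Hochberg adjusted within each library, and called at an adjusted p under 0.05 in the same direction in both. Peak density outside promoter windows, in gene bodies extended by 10 kb, and differences between libraries were given as percentiles among 10000 random lists of the same size, matched in 20 bins of gene length or height. Footprints inside peaks, extended by 5 bp, were searched for each consensus on both strands and compared with 1 window of equal length per footprint from the same peak outside footprints, for 261657 footprints in replicate 1 and 159694 in replicate 2 with room for a window. The test was again Fisher's exact test with Benjamini-Hochberg adjustment. Footprints of a peak are not independent, so these p-values are too small. A consensus finds only sites near the ideal sequence.

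Genes were named as follows: in each list, up to 4 members with the highest mean promoter height and, in lists called less accessible, up to 2 without a peak in either library, first in alphabetical order; the nearest protein-coding gene of the 10 highest shared peaks over 1000 bp from any start site; the 10 protein-coding genes with the most such peaks; and Xist. Some genes under this rule and 1 motif are not reported here. Alternatives covered the peak list, the highest-scoring 50% of peaks, equal numbers of peaks, the overlap required, the promoter window of 1000 bp, the annotation, matching on promoter CpG content, gene bodies alone, the footprint extension, footprints outside promoters, shuffled consensus letters, and each library alone. Matching on CpG content used the ratio of observed to expected CpG at the promoter, so GC content was not matched. Copies of peaks in the genome were searched with BLAST+ 2.17.0, at 90% identity over 80% of the length, with a word size of 20.

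The methods were tested on the deposited peaks and on simulated data. Among the 122729 deposited peaks of replicate 1, the total number overlapping replicate 2 differed from that of bedtools by 0. In 100 simulated data sets over 21938 genes, 100% of lists with a peak at every member were called, 98% of those at 5% of members and 0% of those at the background share. Libraries were simulated as independent, while of the 12806 genes with a promoter peak in replicate 2, 12726 had one in replicate 1. The 0% may therefore understate false calls under the rule of both libraries. Of 8400 planted consensus sites, 100% were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.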

Results

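DNase-seq measures where chromatin is open: the enzyme DNase I cuts accessible DNA, and sites of frequent cutting are called as peaks, while short protected stretches within them are called as footprints of bound protein. It was applied to the right cerebral cortex of 10-day-old female B6CASTF1/J mice, the first-generation offspring of a cross between the C57BL/6J and CAST/EiJ strains. The labels name 2 animals, here replicate 1 and replicate 2, with 1 library each, and 1 group. No second tissue, age or treatment was analysed here, so the comparisons are between the libraries and between genes or sites within a library. All coordinates are on mm10. Numbers of sequenced reads were not used here, and the depth of each library is unknown. The peak heights were whole multiples of a step of 0.00362 in replicate 1 and 0.00751 in replicate 2, a ratio of 2.08, so 1 unit of height stood for more reads in replicate 1 if a step is the same number of reads in both.

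Replicate 1 held 122729 peaks and replicate 2 held 68111, a mean of 95420 ± 38621 (SD, n = 2) and a ratio of 1.80. The peaks covered 22.96 Mb (0.842% of the genome) in replicate 1 and 13.1 Mb (0.482%) in replicate 2, with median widths of 180 and 200 bp. Of the peaks of replicate 2, 86.0% overlapped a peak of replicate 1 (95% Wilson interval 85.7 to 86.3%), against 1.78% for the same peaks placed at random. Of the peaks of replicate 1, 47.9% overlapped a peak of replicate 2 (47.6 to 48.2%), against 1.01% at random. These intervals cover counting error only. Sharing followed peak height: 94.4% of the highest 25% of replicate 1 peaks were shared and 4.29% of the lowest 25%, against 99.6% and 61.6% in replicate 2. With the number of peaks made equal, the shares were 73.8% and 73.7%. Across the 58789 shared peaks, which are not independent replicates, heights in the libraries had a Spearman rho of 0.891. The median over these peaks of the log2 height ratio of replicate 1 to replicate 2 was 0.56. Over the 12726 protein-coding genes with a promoter peak in both libraries, the median log2 ratio of promoter heights was 1.09. The SD of a promoter height below therefore includes this general difference between the libraries and is not a spread particular to the gene.

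**Figure D1:**
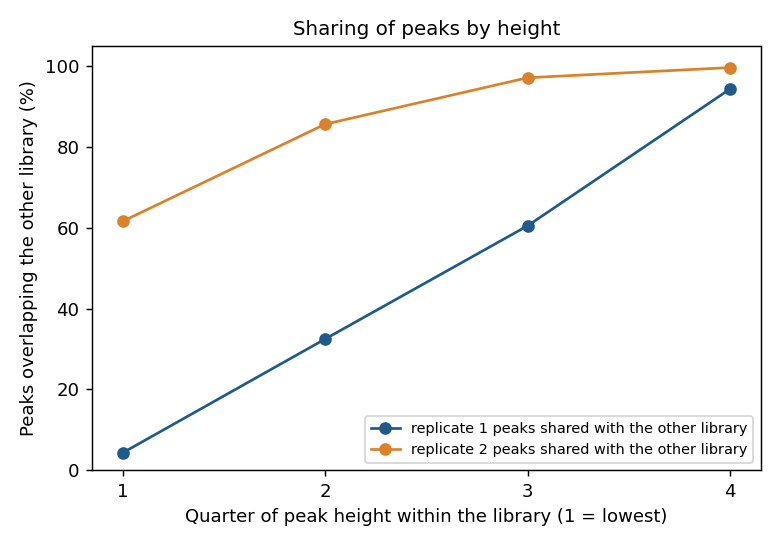
Share of the peaks of each library that overlapped a peak of the other by at least 1 bp (y axis, %), with peaks grouped by height within the library into classes of 25% (x axis). The share rose with height in both libraries, from 4.29% to 94.4% in replicate 1 and from 61.6% to 99.6% in replicate 2.

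Peaks lay at promoters far more often than the genome's composition would give. Peak centres within 500 bp of the transcription start site of a protein-coding gene made up 23.4% ± 4.50 of peaks (SD, n = 2), while such windows cover 1.963% of the genome, an 11.9-fold difference. Exons held 5.03% ± 1.36 of the centres and cover 2.83% of the genome, introns held 33.4% ± 3.66 and cover 33.7%, and intergenic sequence held 38.1% ± 0.528 and covers 61.5%. The promoter share was 20.2% in replicate 1 and 26.6% in replicate 2, and this order turned with equal numbers of peaks, at 29.9% and 26.6%. Among 21938 protein-coding genes, 14248 (64.9%) had a promoter peak in replicate 1, 12806 (58.4%) in replicate 2 and 12726 (58.0%) in both.

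**Figure D2:**
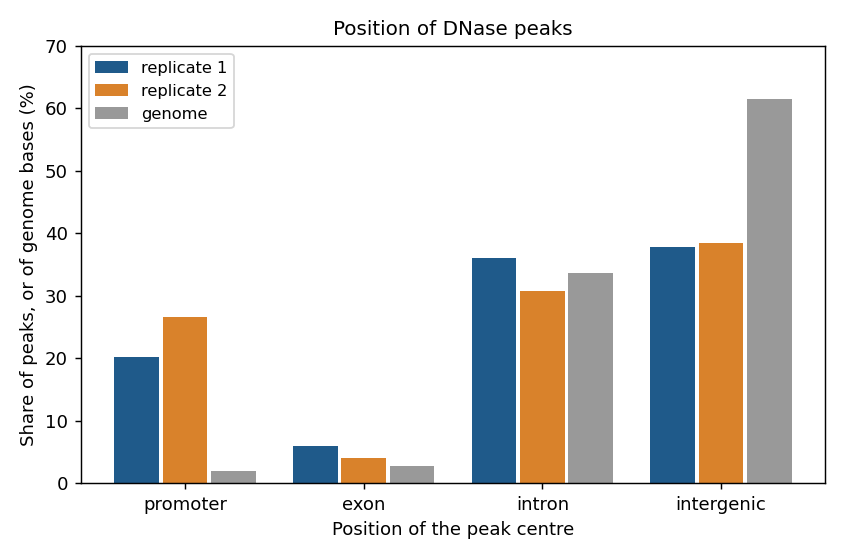
Share of peak centres in each class of position (y axis, %) for replicate 1 and replicate 2 (1 library each, no error bars), beside the share of genome bases in that class. Promoters held 20.2% and 26.6% of the peaks and cover 1.963% of the genome.

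The pan-neuronal, activity-regulated and housekeeping lists had a promoter peak at every member in both libraries. All 12 pan-neuronal and synaptic genes had a promoter peak in both, against 64.9% of other protein-coding genes in replicate 1 and 58.4% in replicate 2 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 20 lists, adjusted p = 0.0282 and 0.00586). The highest mean heights among them were at Syt1, a calcium sensor of synaptic vesicle release (4.96 ± 2.72, SD, n = 2), Gria2, an AMPA receptor subunit (4.75 ± 3.23), Grin1, an NMDA receptor subunit (4.65 ± 2.74), and Tubb3, a neuronal tubulin (4.60 ± 3.06). All 12 activity-regulated genes had a promoter peak in both libraries, with the same p-values. Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984), reached 8.37 ± 4.31, Homer1, a postsynaptic scaffold, 8.27 ± 4.0, Arc, an effector of synaptic plasticity, 6.35 ± 3.44, and Junb, an AP-1 subunit, 6.21 ± 3.07. At Egr1 the highest peaks of the libraries were different sites that did not overlap. The 12 housekeeping genes had the same count and p-values, and the highest mean height of any list member apart from Kdm6a was 15.3 ± 5.80 at Rplp0, a ribosomal protein. Ywhaz followed with 11.1 ± 4.82, Ppia with 10.2 ± 4.16 and Tbp, the TATA-binding protein, with 9.21 ± 4.34, the last at a promoter shared with Psmb1. Random lists were also matched on promoter CpG content, taken as the ratio of observed to expected CpG. They had shares of 94.1% and 87.5% for activity-regulated genes, 95.3% and 89.4% for housekeeping genes and 86.1% and 77.8% for pan-neuronal genes. Against these, even the highest possible share of 100% could not be called in lists of 12, so that matching does not tell whether these calls depend on CpG content.

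Liver, Hox, skeletal muscle and lymphocyte genes had promoter peaks less often than other genes. None of the 12 liver genes had a promoter peak in either library (adjusted p = 3.42e-05 and 5.39e-04 by Fisher's exact test), Alb and Ahsg, which encode plasma proteins, among them. Hox genes, which pattern the trunk and hindbrain, had a peak at 0 of 14 promoters in replicate 1 and 1 of 14 in replicate 2 (adjusted p = 8.39e-06 and 9.63e-04, Fisher's exact test). The exception was Hoxc10, with a height of 0.503 in replicate 2, while Hoxa13 had no peak. Of the 12 skeletal muscle genes, 1 had a peak in each library (adjusted p = 5.31e-04 and 0.00321, Fisher's exact test). It was Mylpf, a myosin light chain, at 5.62 ± 1.99, where the highest peaks of the libraries did not overlap and also lay at the promoter of Tbc1d10b. Acta1 and Actn3, of the muscle filaments, had no peak. Of the 10 lymphocyte genes, 2 had a peak in replicate 1 and 1 in replicate 2 (adjusted p = 0.0195 and 0.00586, Fisher's exact test). Lck, a T-cell kinase, reached 3.08 ± 1.82, and Zap70, another T-cell kinase, had a peak of 0.134 in replicate 1 only, while Cd2 had no peak. Against random lists matched on CpG content, Hox and skeletal muscle genes remained called. Lymphocyte genes stood at percentiles 10.7 and 6.54 and were not called. Liver genes stood at percentiles 1.88 and 5.84 with 0 of 12, the lowest possible count, so they could not have been called with that matching. With a promoter window of 1000 bp, skeletal muscle genes were not called. The list of diencephalon, midbrain and hindbrain genes (5 and 3 of 14) and that of choroid plexus and ependyma (2 and 1 of 8) were called with CpG matching and with the window of 1000 bp, but not against all other genes with the window of 500 bp and all peaks. Against all other genes with that window, the first of these lists was called in the highest-scoring 50% of peaks and with equal numbers of peaks. Bases at a deposited base-wise FDR of 0.05 or less, a looser threshold, lay at 0 and 1 liver promoters in replicate 1 and replicate 2, 3 and 1 Hox, 4 and 3 skeletal muscle and 3 and 1 lymphocyte promoters. They lay at 10 and 5 of the 14 diencephalon, midbrain and hindbrain promoters and at 6 and 2 of the 8 of choroid plexus and ependyma, against 70.7% and 64.5% of all protein-coding genes. Actn3 held such a base in both libraries, Alb in replicate 2 and Cd2 in replicate 1. Among diencephalon, midbrain and hindbrain genes, Pax5 (1.80 ± 0.698), Tcf7l2 (1.78 ± 0.871), Tph2 (1.40 ± 0.0753) and En2 (0.411 ± 0.581) had the highest means, the last with a peak in replicate 1 only. In choroid plexus and ependyma, Foxj1, the regulator of motile cilia, stood at 8.73 ± 2.96. Aqp1, a water channel, stood at 0.470 ± 0.665, with a peak in replicate 1 only.

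**Figure D3:**
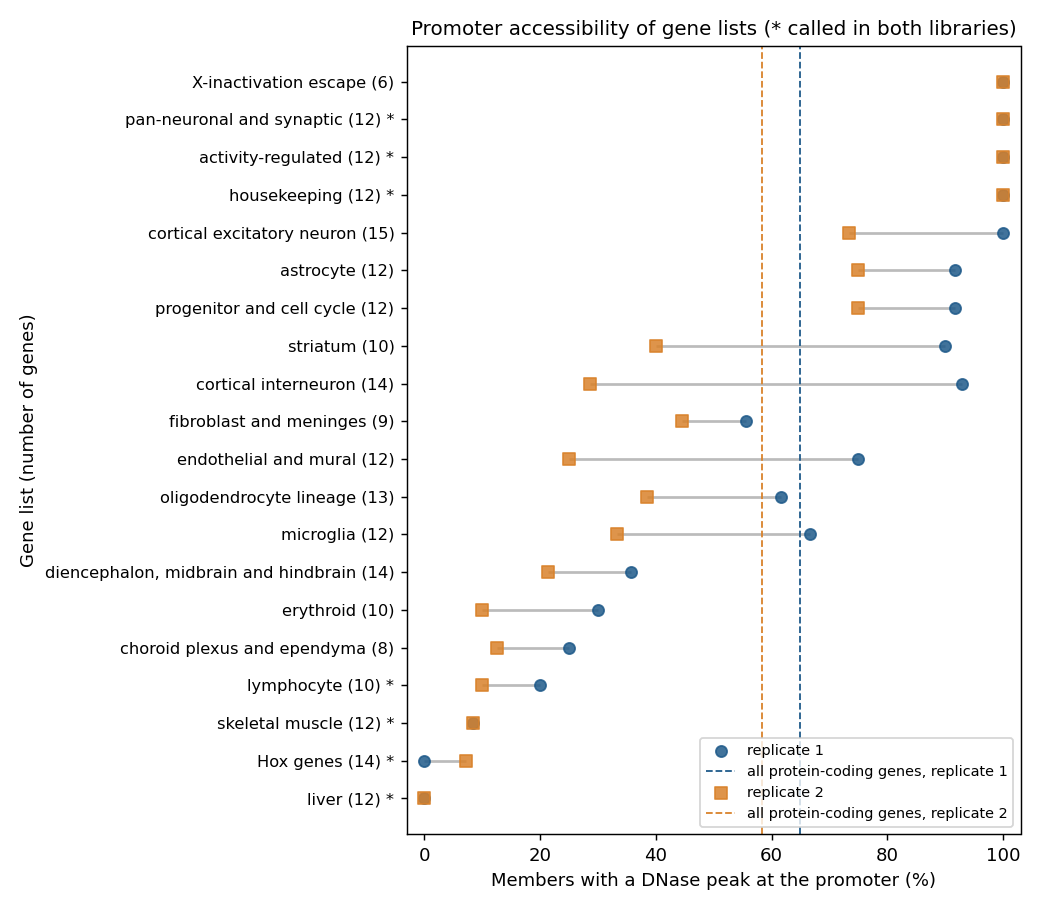
Share of the members of each gene list with a promoter peak (x axis, %) in replicate 1 and replicate 2 (1 library each), with the share among all protein-coding genes as dashed lines. Asterisks mark the 7 lists that passed an adjusted p of 0.05 in the same direction in both libraries, from 0% for liver genes to 100% for 3 lists.

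Markers of the cell types of the cortex had promoter peaks at between 25% and 100% of list members. All 15 excitatory neuron genes had a promoter peak in replicate 1 (adjusted p = 0.0101, Fisher's exact test) and 11 in replicate 2 (adjusted p = 0.376, Fisher's exact test), so the list passed in replicate 1 alone; a difference between the libraries was not tested. Nrgn, a postsynaptic calmodulin-binding protein, reached 3.98 ± 2.15, Lhx2, a transcription factor of the cortical primordium, 3.80 ± 1.93, Camk2a, a synaptic kinase, 3.61 ± 1.30, and Rorb, a marker of layer IV, 3.24 ± 1.73. Interneuron genes had 13 and 4 of 14 promoters with a peak, 92.9% and 28.6%, the largest gap among the lists, and passed in neither library (adjusted p = 0.0528 and 0.0538, Fisher's exact test). Adarb2 (1.62 ± 0.575), Dlx6 (1.57 ± 1.11), Pvalb (1.23 ± 0.484) and Dlx5 (1.05 ± 1.48) led it, the last with a peak in replicate 1 only. At the base-wise FDR of 0.05, 13 and 8 of the 14 promoters held an accessible base. Against random lists matched on CpG content, interneuron genes stood at percentiles 92.6 and 0 in replicate 1 and replicate 2, excitatory neuron genes at 99.7 and 43.0, and microglial genes at 99.5 and 60.7. Astrocyte genes had peaks at 11 and 9 of 12 promoters, led by Glul, glutamine synthetase (6.89 ± 3.85, a promoter shared with Teddm2), Nfia (6.01 ± 3.31), Sox9 (4.28 ± 2.30) and Gfap (2.64 ± 1.03). The oligodendrocyte lineage had 8 and 5 of 13, with Pdgfra, the receptor of its precursors, at 2.49 ± 0.862, Olig1 at 2.39 ± 1.03, Olig2 at 2.06 ± 1.23 and Cnp at 1.43 ± 0.710. At Pdgfra and at Cnp the highest peaks of the libraries did not overlap. Microglial genes had 8 and 4 of 12, among them Sall1 (1.89 ± 1.19), C1qa (0.727 ± 0.179) and Cx3cr1 (0.611 ± 0.0674). Endothelial and mural genes had 9 and 3 of 12, and Foxc1 (0.803 ± 0.190), Rgs5 (0.799 ± 0.164), Pdgfrb (0.693 ± 0.980, with a peak in replicate 1 only) and Kcnj8 (0.537 ± 0.228) led them. None of these lists passed in both libraries in the main setting. Excitatory neuron genes were called more accessible in both with the larger list (mean difference from other genes 30.0 percentage points), and endothelial and mural genes less accessible in both in the highest-scoring 50% of peaks (-43.1 points).

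The remaining lists were not called in the main setting either. Progenitor and cell cycle genes had peaks at 11 and 9 of 12 promoters, with Top2a (5.81 ± 1.70), Cdk1 (5.50 ± 2.11), Ccnb1 (5.43 ± 3.10) and Mki67 (3.83 ± 3.0) highest. Striatal genes had 9 and 4 of 10, with Rgs9 (4.84 ± 2.54), Drd1 (2.38 ± 0.964) and Ppp1r1b (1.78 ± 2.52) among the highest, the last with a peak in replicate 1 only. The striatal list stood at percentiles 56.1 and 0.095 of lists matched on CpG content. Fibroblast and meningeal genes had 5 and 4 of 9, with Col1a1 (3.25 ± 1.20), Foxc2 (1.61 ± 0.497), Tbx18 (0.871 ± 0.319) and Aldh1a2 (0.80 ± 0.25) highest. Erythroid genes had 3 and 1 of 10, among them Epor (1.16 ± 1.64) and Tal1 (0.412 ± 0.583), each with a peak in replicate 1 only, and were called less accessible in both libraries in the highest-scoring 50% of peaks (mean difference from other genes -45.6 percentage points). The difference in log2 promoter height between the libraries, taken over members with a peak in both, lay within the central 95% of random lists matched on height for all 14 lists with at least 3 such members, the lowest being housekeeping genes at percentile 4.68. This leaves out members with a peak in 1 library only, so that 4 of 14 interneuron, 3 of 12 endothelial and mural and 4 of 10 striatal genes entered, and it does not show that the lists were alike in the libraries.

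Away from promoters, the gene bodies and 10 kb flanks of activity-regulated genes held a median of 5 and 2 peaks, at percentiles 99.985 and 99.5 among 10000 random lists matched on gene length, and housekeeping genes 2.5 and 1.5 peaks, at percentiles 98.1 and 98.6. Excitatory neuron genes stood at percentile 99.9 in replicate 1 and 74.7 in replicate 2, and microglial genes at 96.5 and 97.51. Like excitatory neuron genes, 3 other lists were above the central 95% in replicate 1 only. These were oligodendrocyte lineage (99.2 and 58.0), astrocyte (98.4 and 91.2) and progenitor and cell cycle genes (98.1 and 82.4). Counted in gene bodies alone, or with equal numbers of peaks, activity-regulated genes were the only list above the central 95% in both libraries. In the highest-scoring 50% of peaks, activity-regulated and astrocyte genes were above it in both and housekeeping genes were not. The genes with the most shared peaks over 1000 bp from any start site had annotated spans of 604 to 4435 kb. They included Asic2, an acid-sensing channel (33 peaks in each library, chromosome 11, 80880169 to 81968457), Rbfox1, a neuronal splicing factor (32 in each), Kalrn, a signalling protein of dendritic spines (32 and 31), Nav2 (31 in each), Camta1 (31 and 30), Csmd1 (28 and 27) and Lsamp, a limbic adhesion protein (27 in each). Gm20388 (164 and 165), Fgfr2 (68 and 67) and Gm37240 (27 in each) also ranked among the 10, where the annotated spans were 4435, 2961 and 1391 kb and cross other genes.

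The 10 highest shared distal peaks were led by a site in an intron of Mid1 (chromosome X, 169998221 to 169998400; height 28.2 ± 16.2, SD, n = 2). Exonic sites followed in Cers5 (chromosome 15, 99735821 to 99736040; 27.5 ± 3.37) and Lars2 (chromosome 9, 123461921 to 123462080; 23.02 ± 0.832). Sites outside protein-coding genes lay nearest, among such genes, to Pak3 (chromosome X, 143482981 to 143483140; 21.1 ± 4.47), Tra2a (19.4 ± 0.735), Gm8797 (18.8 ± 10.7), Cstad (14.4 ± 9.54) and Tle2 (14.4 ± 5.03). Their distances from these genes were 35530, 7393, 109151, 49668 and 2820 bp. The site assigned to Cstad lay within 2 annotated lincRNA genes. Ubqln1 held one in an exon (17.0 ± 1.56) and Il31ra one in an intron (16.3 ± 2.47). The sites at Mid1, Lars2, Tra2a, Gm8797 and Il31ra had 4, 4, 2, 15 and 7 near-identical copies elsewhere in the genome, over at least 80% of their length at 90% identity or more, so their heights are uncertain. None of the 10 held the CTCF consensus.

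Footprints numbered 473661 in replicate 1 and 251948 in replicate 2, a mean of 362804 ± 156775 (SD, n = 2), with a median width of 10 bp in both. Of these, 58.1% and 65.3% lay within peaks. In peaks shared by the libraries, 60.3% of replicate 1 footprints and 74.2% of replicate 2 footprints overlapped one of the other library, against 43.2% and 50.03% when footprints were moved at random within their peak.

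The consensus of the insulator protein CTCF was enriched in footprints. It was present in 1.29% of replicate 1 footprints and 2.35% of replicate 2 footprints, 125-fold and 144-fold more often than in windows of equal length from the same peaks. Of the 21 motifs searched, 12 were enriched in both libraries (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). RFX, the regulator of cilia and of MHC class II genes, stood at 36.6 ± 9.59-fold (SD, n = 2), NRF1 at 28.2 ± 2.99, EGR at 22.1 ± 8.84, CREB, a mediator of activity-dependent transcription, at 13.4 ± 5.61, SP/KLF at 9.92 ± 0.952 and the neuronal gene repressor REST at 6.70 ± 2.40. NFI occurred in 127 and 45 footprints and in none of the windows, at least 42.3-fold and 15-fold higher when the windows are set to 3 counts per library. The NEUROD/NEUROG E-box, bound by neurogenic factors, was enriched 2.68 ± 0.521-fold, YY1 2.52 ± 1.08-fold and ETS 1.52 ± 0.391-fold. The weakest adjusted p among the 12 was 0.00931, for REST in replicate 2. Few windows held some of these motifs: 5 and 6 for RFX, 13 and 10 for NRF1, 11 and 14 for EGR and 5 and 3 for REST. The folds of these motifs are therefore imprecise, which the SD over the libraries does not show. Footprints held GATA (0.369 ± 0.0160-fold), PU.1 (0.515 ± 0.115), the POU octamer (0.558 ± 0.126), LHX/homeobox (0.627 ± 0.0648) and SOX (0.781 ± 0.0908) less often than windows did. AP-1 (0.857 ± 0.128), MEF2 (0.893 ± 0.0686) and HNF4 (0.938 ± 0.0884) were not called, and HNF1 was found in no footprint or window. Footprints were richer in G and C than the windows, 60.1% against 54.3% in replicate 1 and 59.2% against 53.7% in replicate 2. Against shuffles of their own letters, 17 motifs were enriched, SOX, PU.1, the POU octamer, AP-1 and MEF2 among them, while EGR fell to 1.49-fold and 2.06-fold. Without the extension of footprints REST and YY1 were not called and 10 motifs were enriched. In that setting AP-1 (0.490-fold and 0.725-fold) and MEF2 (0.412-fold and 0.379-fold) were called depleted in both libraries. Outside promoters REST, YY1 and ETS were not called, 9 were enriched and the POU octamer was no longer called depleted. Fewer sites entered, such as 5 footprints of replicate 2 with REST without the extension and 8 with YY1 outside promoters. The mean log2 fold of REST was 2.55 without the extension and 2.18 outside promoters, against 2.55 in the main setting. That of YY1 was 1.21 and 2.23 against 1.26, and that of ETS outside promoters 0.32 against 0.58.

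**Figure D4:**
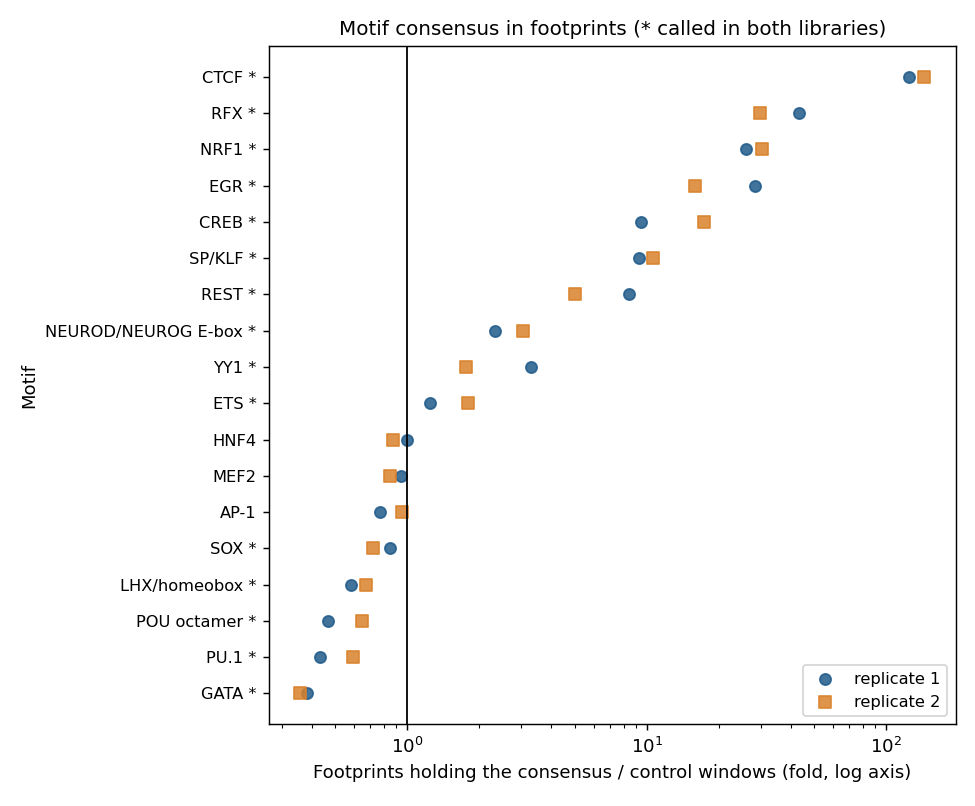
Frequency of each motif consensus in footprints relative to windows of the same peaks (x axis, fold, log axis) in replicate 1 and replicate 2 (1 library each). Asterisks mark motifs that passed in both libraries, from GATA at 0.369-fold to CTCF at 134-fold on average. NFI and HNF1, absent from the windows, and 1 motif that is not reported are not drawn.

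The sex chromosomes were examined because the labels give both animals as female. None of 183 protein-coding genes on Y had a promoter peak in either library, and Y held 35 peaks in replicate 1 and 5 in replicate 2. X held 14.7 and 9.80 peaks per Mb against 48.8 and 26.97 on autosomes, ratios of 0.301 and 0.363. Promoter peaks on X had a median height of 2.43 in replicate 1 and 1.43 in replicate 2, against 5.25 and 2.73 on autosomes, a ratio of 0.463 (95% bootstrap interval over genes 0.410 to 0.530) and 0.526 (0.468 to 0.570). All 6 genes of the X-inactivation escape list, which also holds Xist, had promoter peaks. Kdm6a, a histone demethylase (chromosome X, 18162575 to 18279936), reached 20.5 ± 10.9 (SD, n = 2), Kdm5c, another histone demethylase, 11.01 ± 6.61, 5530601H04Rik 6.96 ± 4.63 at a promoter shared with Pbdc1, and Ddx3x, an RNA helicase, 6.10 ± 3.11. Xist, the RNA that coats the inactive X (chromosome X, 103460366 to 103483254), had a promoter peak of 2.12 in replicate 1 and 1.14 in replicate 2.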

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

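The tests of depth and of DNA of a male animal, the random Y sequence used as background and the split of the Y peaks by position were chosen after the results they bear on were seen. The labels give no biological difference between the animals, so none was tested for the difference between the libraries.

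Peaks on Y stood out because both animals are labelled female: 35 in replicate 1 and 5 in replicate 2, a signal outside the main measurement. DNA of a male animal is argued against, since the Y protein-coding promoters with a peak numbered 0 of 183, among them Kdm5d, Uty, Ddx3y and Eif2s3y, and none held a base at an FDR of 0.05 or less. For reads from similar sequence, 60% of the Y peaks in replicate 1 and 100% in replicate 2 had a copy on another chromosome, above the bound of 50% set beforehand. But 50 of 100 random windows of Y had one too. For the 35 peaks of replicate 1 no difference from that share was detectable (two-sided Fisher's exact test, p = 0.332). In replicate 2 all 5 peaks had a copy, the highest possible count, with p = 0.0580 by Fisher's exact test. With 5 peaks that test could not have passed 0.05, so it decides nothing there. The source of the Y peaks therefore cannot be told apart from this measure. By position, a copy on another chromosome was found for 10 of the 24 replicate 1 peaks within Y 90717622 to 90745320 and for all 11 outside it, and in replicate 2 for the 1 within and all 4 outside.

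Replicate 1 had more peaks than replicate 2 and higher ones at shared sites, although the median over all its peaks was lower (0.792 against 0.946). Depth alone, which multiplies all heights by the same factor, is argued against, because among shared peaks of similar height outside promoters the log2 height ratio was higher in the GC-richest 25% than in the poorest by 0.37 to 0.49 in 4 height classes (95% bootstrap intervals over peaks from 0.35 to 0.52), while a part of depth in the number of peaks stays open. A candidate explanation is a GC bias between the libraries. Outside promoters the ratio rose from 0.13 in the GC-poorest 25% of shared peaks to 0.72 in the richest. This difference of 0.58 was not taken at equal height. The ratio also rose with height, from the lowest to the highest of the 4 classes. It went from -0.08 to 0.44 in the GC-poorest 25% and from 0.30 to 0.93 in the richest. The cause of this rise was not tested, so a GC bias is not the only candidate. At equal GC, promoter peaks exceeded others by 0.036 at 45 to 50% and 0.057 at 50 to 55% GC, and by 0.20 at 60 to 65%, so GC content may not account for all of the height difference at GC-rich sites.

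Promoter peaks were lower on X than on autosomes. The promoter CpG ratio (observed to expected CpG) as the whole cause is argued against. X promoters stood at 0.604 and 0.599 times the height of autosomal promoters matched on it. Without matching, X promoters stood at 0.463 and 0.526 times the autosomal height, so a part of the CpG ratio stays open. GC content was not matched and stays open too. Repeats as the whole cause are argued against too, with ratios of 0.510 and 0.543 among genes with under 10% of repeat bases. A hypothesis that stays open is that one X is silenced in each cell, which would lower the average over both copies except at genes that escape. The 6 genes of the escape list, fixed beforehand and with Xist among them, had a median height 3.83 and 2.67 times that of other X genes with a promoter peak, at percentile 99.98 or above among random X lists. Against X lists matched on promoter CpG ratio they stood at percentiles 100 and 99.83. They also stood at 1.77 and 1.39 times the autosomal median, which escape from silencing does not account for, so other properties of these genes may raise them. Apart from the CpG ratio against other X genes, such properties were not tested.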

How the results depend on the processing

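The comparison of the stricter with the larger list, equal numbers of peaks in the annotation, the larger list for promoters and sex chromosomes, and each library alone for peak density and sex chromosomes were chosen after seeing the data. Of 67 alternative values for the main results, 41 stayed within the tolerance of their kind (1.5 times for numbers of peaks, footprints, lists and motifs, the 95% interval for sharing and correlation, 1 SD for annotation and sex chromosomes) and 26 moved; the cause was not tested except where fewer peaks enter by construction. Peaks per library averaged 164906 in the larger list and 47709.5 in the highest-scoring 50%, with 68111 to 122729 for each library alone. Sharing of replicate 1 and replicate 2 peaks was 41.03% and 73.9% with a reciprocal overlap of 50%, 73.8% and 73.7% with equal numbers, 54.1% and 96.8% in the highest-scoring 50%, 46.7% and 81.9% in the larger list, and 63.1% and 94.1% for the stricter against the larger list. The height correlation was 0.848 outside promoters and 0.901 with reciprocal overlap; neither it nor sharing can be computed with 1 library. The promoter share was 28.9% with the window of 1000 bp, 34.4% in the highest-scoring 50% and 28.3% with equal numbers, and 20.2 to 26.6% for each library alone. Footprints inside peaks averaged 219994, and each library alone had 251948 to 473661. Peaks on Y averaged 50.5 in the larger list, with 5 to 35 for each library alone, and the density of X over autosomes was 0.301 to 0.363.

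More accessible lists fell from 3 to 0 with CpG matching, where lists already at 100% could not be called, and were 3 to 4 for each library alone. Less accessible lists rose from 4 to 7 in the highest-scoring 50%, the same 4 among them, and were 4 to 7 for each library alone, 7 without replicate 1. Lists dense in peaks numbered 1 with gene bodies alone, 1 with equal numbers, 2 in the highest-scoring 50%, where astrocyte replaced housekeeping genes, and 3 to 6 for each library alone, 6 without replicate 2. Depleted motifs fell from 5 to 2 against shuffled letters, and each library alone gave 12 enriched and 5 to 6 depleted; enriched motifs numbered 10 without extension, 9 outside promoters and 17 against shuffled letters. For single lists, 10 of 140 alternatives reversed, in percentage points against other genes (for CpG matching, against matched random lists): with the larger list, interneuron 8.34, microglia 8.34 and endothelial 4.17; with CpG matching, microglia 19.4, progenitor -8.79 and striatum -18.9; with replicate 1 alone, interneuron 27.9, microglia 1.72 and endothelial 10.1; with replicate 2 alone, striatum -18.4. The other library alone kept the main direction, at -29.8, -25.1, -33.4 and 25.1. For single motifs, 6 values reversed, all against shuffled letters, in log2: MEF2 1.83, AP-1 0.81, SOX 0.77, POU 2.57, HNF4 0.65 and PU.1 1.05. Of the other alternatives, 43 for lists and 76 for motifs kept a call, 68 and 14 were uncalled before and after, 12 lost a call and 16 gained one. The lists hold 6 to 15 genes, so 1 promoter moves a share by several points.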

Other observations

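The gene families, the ranking of short genes and the comparison of unshared peaks were chosen after the data were seen. Families were taken by symbol, and 12 were tested with two-sided Fisher's exact tests against all other protein-coding genes, Benjamini-Hochberg adjusted within each library. They were not matched on promoter CpG content, and a loss of reads at similar copies was not tested. Members of a family are not independent, so these p-values may be too small.

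Receptors of the nose and genes of surface epithelia had few open promoters. Of 1093 olfactory receptor genes, 13 (1.19%) had a promoter peak in each library, against 68.3% and 61.4% of other genes. Of 327 vomeronasal receptor genes, 2 had one in each (adjusted p = 1.63e-145 and 7.25e-121, Fisher's exact test). Keratins had 6 and 3 of 49 (adjusted p = 6.74e-14 and 2.41e-14, Fisher's exact test) and defensins 1 and 0 of 64 (adjusted p = 2.96e-27 and 1.15e-24). Clustered protocadherins, which are expressed in neurons and give each its surface identity, also had few, 15 and 9 of 55 (27.3% and 16.4%, adjusted p = 2.55e-08 and 4.74e-10, Fisher's exact test), with median heights of 0.579 and 0.413 where present.

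Zinc finger genes named Zfp had 318 and 311 of 365 promoters open (87.1% and 85.2%, adjusted p = 1.97e-21 and 3.32e-28, Fisher's exact test) and ribosomal protein genes 76 of 79 in both libraries (96.2%, adjusted p = 7.73e-11 and 2.41e-14). Potassium channel genes had 78 of 92 in replicate 1 (84.8%, adjusted p = 5.75e-05, Fisher's exact test) and 57 in replicate 2 (62.0%, adjusted p = 0.631), so the call rests on replicate 1. GABA-A receptor (14 and 9 of 19), ionotropic glutamate receptor (16 and 11 of 18), metabotropic glutamate receptor (7 and 4 of 8) and synaptotagmin genes (15 and 14 of 17) passed in neither library. Among protein-coding genes under 100 kb, the most shared distal peaks were at Nfic, an NFI transcription factor (17, chromosome 10, 81396186 to 81455635), Tnrc18 (12), Bahcc1 (11) and Itpkb (11).

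Of the peaks of replicate 1, 36.9% had no counterpart even in the larger list of replicate 2. Their centres lay at promoters in 11.4%, in exons in 8.53% and in introns in 43.1%, against 25.4%, 4.52% and 31.8% for the others, and their median height was 0.286 against 1.21. In replicate 2, where 5.85% had none, the shares were close: 26.9% at promoters, 4.06% in exons and 31.6% in introns, against 26.6%, 4.07% and 30.8% for the others.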
